A study of Mus musculus with 9 samples.

How the data were processed

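Gene expression was measured on 9 arrays, 3 at each of days 4, 7 and 21 of differentiation. Mouse embryonic stem cells carried a transgene that places green fluorescent protein under control of the promoter of Afp, the gene for alpha-fetoprotein. They were grown as embryoid bodies, aggregates in which stem cells form derivatives of the germ layers, and cells positive for the Afp reporter were collected by flow cytometry, per the labels' protocols. Total RNA was labelled with an Affymetrix kit made for very small RNA inputs, per the same protocols. Such labelling amplifies the RNA in more than 1 round, so ratios between dim transcripts can be distorted.

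The deposited values are log2 signals per probe set, made by the authors with Affymetrix Expression Console and RMA per the submitters' processing notes. Versions of these tools are not given in the sources used here. RMA subtracts background, brings the arrays to a common distribution and summarises probes on a log2 scale, so a shift of all transcripts together would be largely removed. The values ran from 1.62 to 13.98 and no pair of arrays held identical values. Arrays give no counting depth, and their number limits the precision. Median signal over all probe sets lay between 5.88 and 5.98 on the 9 arrays.

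The table held 34365 probe sets. Of these, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 9030 were without a symbol here. Only probe sets with 1 symbol were used, and 23328 of them were matched by Entrez gene number to a RefSeq table of mouse assembly GRCm38.p6, which changed 0 symbols. No coordinates are given, because the assembly behind the array annotation is not given in the sources used here. For each gene the probe set with the highest mean signal was kept, which left 22180 genes, 1082 of them with several probe sets. Probe sets of 1 gene were called in opposite directions for 0 genes between days 4 and 7, for 2 genes between days 7 and 21 (Kdf1 and Slc36a4) and for 5 genes between days 4 and 21 (Arhgap26, Cul5, Hif1a, Kdf1 and Zc3h6). None of these is described further, and they are named here because their values were seen to conflict.

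A linear model with a mean per day was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 comparisons share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the 22180 genes of each comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold. Tests were two-sided. Standard errors (SE) of log2 changes come from this model, and SD is the spread of the 3 arrays of a day. The labels do not say that the arrays of a day come from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

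Before the data were examined, 48 gene lists were written from general knowledge, with 1114 distinct genes, of which 1017 were measured (13 to 36 per list). The lists hold 1220 entries, so some genes count in more than 1 list and the lists are not independent. They cover cell lineages, endoderm and liver functions, signalling pathways, cell division, metabolism and stress, and they include markers of other cell types that a sort could hold. Each list was compared with all other genes by limma's camera with the correlation between genes preset at 0.01, adjusted over the 48 lists. Members were also counted as risen or fallen after adjustment over all genes and after adjustment over the list alone. The camera test was repeated with a correlation estimated from the data, and limma's fry tested whether the members moved, on balance, in 1 direction without comparison to other genes.

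Genes are named by a rule fixed before the data were examined. It takes, per comparison, the 6 largest rises and the 6 largest falls among called genes whose groups of 3 arrays did not overlap, leaving out predicted, clone-named and non-coding models, receptor families and immune receptor segments. It adds 14 anchor genes whatever their result, and up to 4 called members of each described list with the largest changes, or up to 2 members where none was called. Genes called in both intervals and the members of lists written later were chosen after their values, or those of related genes, were seen.

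As a reference for background, the signals of 1105 olfactory receptor genes were used, which are silent in most cells. Their 95th percentile lay between 5.91 and 6.19 on the 9 arrays, and a gene with a mean above it on a day is called above background below. Changes to or from a mean below it are set against a floor, so their sizes are those of array signal. This reference was chosen after seeing the data.

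Both procedures were tested on simulated data with the day 4 means of the real genes and the spreads estimated by the model. Noise was drawn independently for each gene, and 200 of the 22180 genes were changed in each comparison. Of genes given a log2 change of 0.5, 23.9% were recovered between days 7 and 4, 31.3% between days 21 and 7 and 20.9% between days 21 and 4. At a change of 1 the shares were 95.5%, 97.0% and 92.5%, and at 2 they were 100% in each. Of the simulated calls, 4.58%, 2.56% and 4.05% were false. Each share at 0.5 and at 1 rests on 67 genes, so differences between the comparisons are not interpreted. A far larger share of genes was called in the real data, and the adjustment depends on that share. The recovered shares therefore need not hold there. All 5 lists that were shifted by 0.5 were called in each comparison, and 0 were called of the unshifted lists that share no member with them (37, 25 and 33 lists). Members of a list do not vary together in such data, so this does not show how camera's preset correlation performs on the real arrays. There, groupings that mixed the days gave up to 16, 18 and 24 list calls, as described below. Such groupings keep part of the day difference, so they do not show it either.

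The alternatives tried were other scalings of the arrays (median centring and quantile normalization), filters on dim genes, other handling of probe sets, a trended and robust prior, array weights, only the arrays of the days compared, stricter thresholds, a block for the replicate number, and leaving out each array in turn.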

Results

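Expression was profiled in cells from embryoid bodies labelled as sorted for the Afp reporter at days 4, 7 and 21, with 3 arrays per day. Afp encodes alpha-fetoprotein, a plasma protein made by the visceral endoderm of the yolk sac and by fetal liver. Correlation across genes, which are not independent replicates, lay between 0.984 and 0.991 for arrays of the same day. It was 0.966 to 0.971 between days 4 and 7, 0.946 to 0.953 between days 7 and 21, and 0.938 to 0.943 between days 4 and 21. The first 2 principal components carried 54.8% and 23.4% of the variance. The purpose that the series title names is the differentiation of endoderm from embryonic stem cells. The 3 comparisons below describe how transcripts differed between the cells sorted on these days. Differentiation is not separated in them from a change in which cells were sorted.

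Between days 4 and 7, most listed transcripts of visceral endoderm, the absorptive epithelium of the yolk sac, rose in the sorted cells. Most listed transcripts of the epiblast and primitive streak fell, and the others did not pass. Cubn (probe set 17381791), which encodes the endocytic receptor cubilin, rose 77.6-fold from a log2 signal of 5.72 ± 0.33 at day 4 (mean ± SD, n = 3 arrays per day), a log2 change of 6.28 ± 0.16 (SE). Apob (17273864), the structural protein of triglyceride-rich lipoproteins, rose 56.8-fold from 6.93 ± 0.21 to 12.76 ± 0.13. Afp itself (17438903) rose 29.4-fold from 5.72 ± 0.18 to 10.60 ± 0.07, with a limma adjusted p of 7.37e-09. Other large rises were those of Slc13a4, a sulfate transporter (29.0-fold), Abcc2, an organic anion exporter (20.4-fold), and Ttr, a carrier of thyroid hormone and retinol-binding protein (19.7-fold). The day 4 means of Cubn, Afp, Abcc2 and Ttr lay below background, so these folds are ratios of array signal to a floor.

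The genes with the largest falls by day 7 were Aplnr, the apelin receptor, at a log2 change of -3.93 ± 0.17 (SE), and Tdgf1, a co-receptor of Nodal, at -3.88 ± 0.10. Gabrb2, a subunit of the GABA-A receptor, changed by -3.72 ± 0.16 and Pkd1l1, a member of the polycystin family, by -3.41 ± 0.13. The interferon-inducible genes Ifi27 and Gbp7 changed by -3.40 ± 0.20 and -3.37 ± 0.09. The 3 day 7 arrays lay on 1 side of the 3 day 4 arrays for each of these genes, and the limma adjusted p was at most 1.68e-06 (Ifi27). The day 7 means of Gabrb2, Pkd1l1, Ifi27 and Gbp7 lay below background, so the sizes and ranks of their falls are set against a floor.

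**Figure D1:**
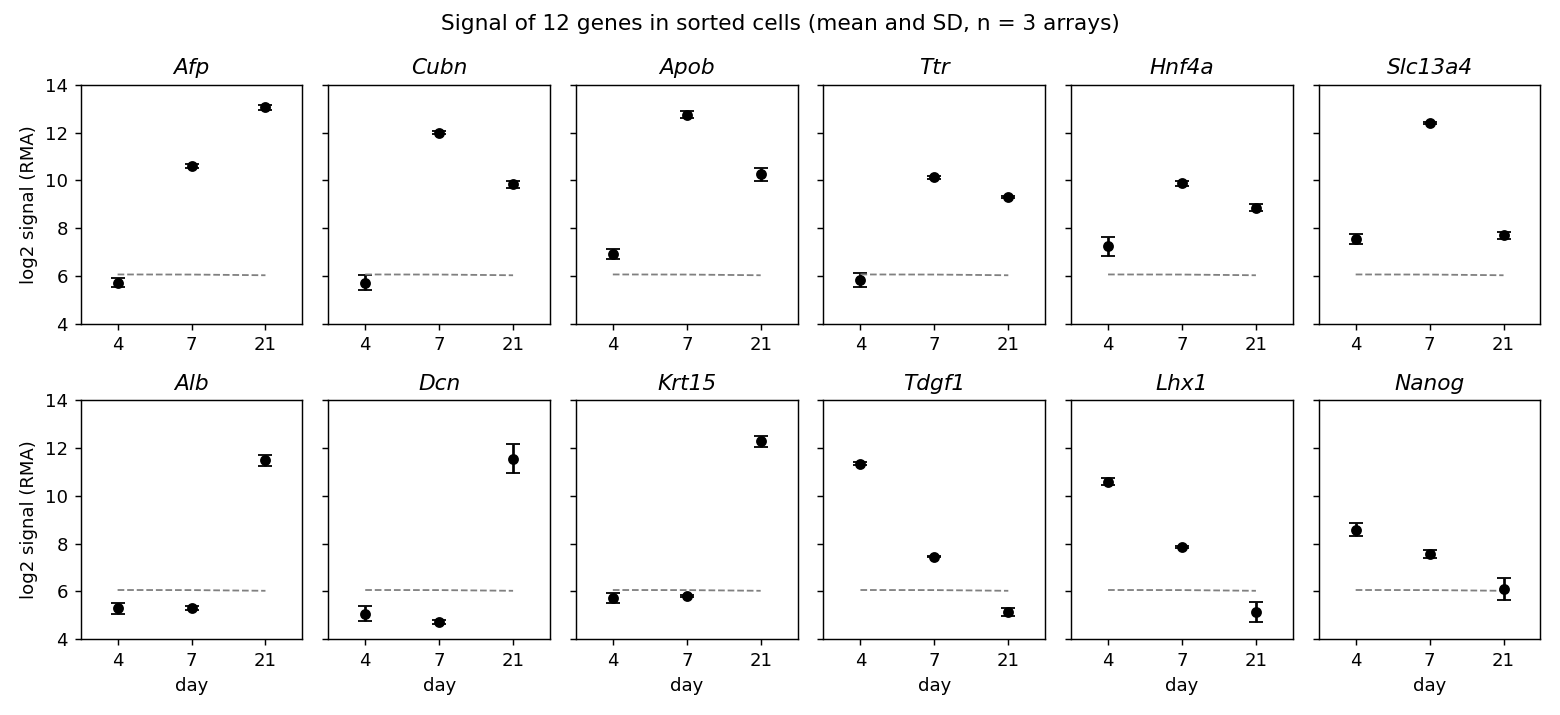
Log2 signal (RMA, vertical axis) of 12 genes in cells labelled as sorted for the Afp reporter at days 4, 7 and 21 (horizontal axis, not to scale in time). Points are means and bars are SD of 3 arrays, and the dashed line is the mean 95th percentile of olfactory receptor genes, at 6.06 on day 4 and 6.03 on day 21. Afp climbs from 5.72 to 10.60 and 13.07, Cubn and Slc13a4 peak at day 7, and Dcn, Krt15 and Alb lie below the line until day 21.

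Of 33 measured visceral endoderm genes, 29 rose, 0 fell and 4 did not pass at day 7 against day 4 (30 up and 1 down adjusted over the list alone), with a median log2 change of 1.70. They included Cubn, Apob, Slc13a4 and Ttr, and the camera adjusted p, 1.02e-40, was the lowest of the 48 lists in this interval. Of 23 apolipoprotein and lipid transport genes, 14 rose and 1 fell, while 8 did not pass (16 and 1 adjusted over the list alone). They included Apom, an apolipoprotein of high-density particles (3.61 ± 0.27), and Mttp, which loads lipid onto apolipoprotein B (3.48 ± 0.11). The camera adjusted p of this list was 2.61e-13. Of 27 lysosome and endocytosis genes, 21 rose, 1 fell and 5 did not pass (24 and 1 adjusted over the list alone; camera adjusted p = 1.04e-20). The lysosomal proteases Ctsh and Lgmn rose by 3.32 ± 0.13 and 2.63 ± 0.12, and Dab2, an endocytic adaptor, by 3.23 ± 0.10. Of 29 hepatic plasma protein genes, 9 rose, 0 fell and 20 did not pass (10 and 0 adjusted over the list alone). The risers included Afp, whose promoter drives the reporter used for sorting, and which counts in this list in every comparison. Others were Rbp4, the plasma retinol carrier (4.25 ± 0.10), and Plg, plasminogen (3.36 ± 0.18). By camera the adjusted p was 1.94e-06, with adjusted p = 0.0742 with an estimated correlation. Ttr and Rbp4 stand in both the hepatic and the visceral endoderm list. Cubn, Apob and Apom stand in both the lipid transport and the visceral endoderm list, so these calls rest partly on the same genes.

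Part of the epithelial, glycolytic and imprinted growth genes also rose in this interval. Of 27 genes of epithelial junctions and keratins, 15 rose, 0 fell and 12 did not pass (19 and 0 adjusted over the list alone), among them the tight junction genes Cldn7 (2.12 ± 0.15), Ocln (1.76 ± 0.12) and Cldn6 (1.70 ± 0.11). Compared with other genes, the list had a camera adjusted p of 2.61e-13, with adjusted p = 0.120 with an estimated correlation. Of 23 hypoxia and glycolysis genes, 13 rose, 0 fell and 10 did not pass (15 and 0 adjusted over the list alone; camera adjusted p = 9.86e-12). Vegfa, an angiogenic growth factor, rose by 1.82 ± 0.09 and Pgk1, a glycolytic kinase, by 1.26 ± 0.11. Of 19 imprinted fetal growth genes, 10 rose, 1 fell and 8 did not pass (10 and 1 adjusted over the list alone), with Dlk1 at 1.91 ± 0.15 and Igf2 at 0.99 ± 0.09. For this list the camera adjusted p was 6.64e-06, with adjusted p = 0.124 with an estimated correlation.

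Among groups that fell at day 7, 13 of 22 epiblast and primitive streak genes fell, 0 rose and 9 did not pass (14 down and 0 up adjusted over the list alone; camera adjusted p = 5.65e-10). Examples were the transcription factors Lhx1 (-2.72 ± 0.18), Mixl1 (-2.60 ± 0.18) and Eomes (-2.37 ± 0.13). Of 17 genes of epithelial-mesenchymal transition, 11 fell, 0 rose and 6 did not pass (12 and 0 adjusted over the list alone), among them Cdh2, N-cadherin (-1.87 ± 0.19). This list had a camera adjusted p of 7.20e-08, with adjusted p = 0.130 with an estimated correlation. Of 24 interferon response genes, 18 fell, 0 rose and 6 did not pass (18 down and 1 up adjusted over the list alone; camera adjusted p = 6.31e-17). Oasl2, Rtp4 and Ifih1, all induced by interferon, changed by -3.07 ± 0.10, -2.74 ± 0.15 and -2.25 ± 0.15. Of 29 DNA replication genes, 8 fell, 0 rose and 21 did not pass (13 and 0 adjusted over the list alone), with Gins1 of the replicative helicase at -0.69 ± 0.10. As a list they had a camera adjusted p of 4.37e-06, with adjusted p = 0.157 with an estimated correlation. Of 21 Notch and Hedgehog genes, 7 fell, 1 rose and 13 did not pass (9 and 2 adjusted over the list alone), with the ligand Jag1 at -2.21 ± 0.13 and the receptor Notch1 at -1.45 ± 0.14. Here the camera adjusted p was 4.39e-04, with adjusted p = 0.124 with an estimated correlation.

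Among the transcription factors fixed as anchors, Hnf4a, a regulator of hepatic and visceral endoderm genes, rose from 7.23 ± 0.40 to 9.89 ± 0.10 by day 7. Sox17 rose by 1.47 ± 0.10 and Gata4 by 1.64 ± 0.13, while the changes of Foxa2 (0.36 ± 0.15) and Gata6 (0.04 ± 0.11) did not pass. Apoa1, the main protein of high-density lipoprotein, rose by 2.21 ± 0.11. Nanog, a pluripotency factor, fell by 1.04 on the log2 scale (limma adjusted p = 0.00832). Changes of Alb (0.02 ± 0.15), Pou5f1 (-0.10 ± 0.17), Cdh1 (0.38 ± 0.16) and the proliferation marker Mki67 (-0.09 ± 0.13) did not pass. Of 19 endoderm transcription factors, 8 rose, 3 fell and 8 did not pass, with the same counts of 8 and 3 adjusted over the list alone. The camera adjusted p of this list was 0.00127, with adjusted p = 0.0594 with an estimated correlation.

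Markers of other cell types were measured in the same arrays. Between days 4 and 7, 9 of 28 cardiac and skeletal muscle genes rose and 0 fell (11 and 0 adjusted over the list alone). These included Tnnc1, a troponin of slow and cardiac muscle (3.21 ± 0.22), and Tnnt2 (1.26 ± 0.09). Camera gave this list an adjusted p of 3.03e-05, with adjusted p = 0.0742 with an estimated correlation. Of 26 mesenchyme and fibroblast genes, 6 fell and 1 rose, the same as adjusted over the list alone, with Twist1 at -1.77 ± 0.13 and Igfbp5 at 2.61 ± 0.11. By camera the adjusted p was 0.0160, with adjusted p = 0.518 with an estimated correlation, and the fry adjusted p was 0.327. Lists of pluripotency (4 of 29 up, 5 down), endothelium (4 of 24 up, 1 down), erythroid cells (1 of 14 up, 2 down), leukocytes (2 of 25 up, 0 down), pancreas (2 of 24 up, 1 down) and intestine (4 of 29 up, 2 down) were not called by camera. Adjusted over the list alone these counts were 4 and 6, 5 and 1, 1 and 2, 2 and 0, 2 and 1, and 4 and 2. Neural genes (1 of 23 up, 6 down, or 3 and 6 adjusted over the list alone) had a median log2 change of 0.02 and a mean of -0.28, and were not called by camera. Of 18 trophoblast genes 0 passed limma's adjusted test, 1 had an unadjusted p under 0.05, and the fry adjusted p was 0.415, with Cdx2 at 0.38 ± 0.19. The medians of the pluripotency and pancreas lists were near 0, and that of pluripotency changed sign with the scaling of the arrays. Without comparison to other genes, fry called leukocyte (adjusted p = 0.0294), intestine (0.0313) and endothelial genes (0.0362) upward and neural genes (0.00929) downward. It did not call pluripotency (0.0926), pancreas (0.136) or erythroid genes (0.288).

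In all, 2983 of 22180 genes (13.4%) were called between days 4 and 7, 1548 higher and 1435 lower at day 7. A change of at least 2-fold was seen for 454 of the higher and 302 of the lower genes. The groups of 3 did not overlap for 6630 genes, against 10% of genes by chance. Camera called 29 of 48 lists, 18 upward and 11 downward. Only 6 calls held with an estimated correlation, those of visceral endoderm, apolipoproteins, lysosome, hypoxia, epiblast and interferon genes.

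From day 7 to day 21, many transcripts of hepatic plasma proteins, of stromal matrix and of epithelial junctions rose in the sorted cells, and most of the visceral endoderm set fell. The camera calls of the stromal and epithelial lists did not hold with an estimated correlation. Alb (probe set 17438886), which encodes albumin, rose 72.9-fold from 5.31 ± 0.08 to 11.50 ± 0.23 (log2 signal, mean ± SD, n = 3 arrays per day). Dcn (17236800), a proteoglycan of connective tissue, rose 114-fold from 4.73 ± 0.09 to 11.56 ± 0.62, and Krt15 (17269358), a keratin of basal epithelial cells, rose 88.3-fold. Afp rose a further 5.53-fold to 13.07 ± 0.11, with a limma adjusted p of 1.78e-07. Krt17 (47.0-fold), the uroplakin-family tetraspanin Upk1b (43.9-fold) and Cym, the milk-clotting protease chymosin (36.4-fold), also rose. All of these except Cym and Afp were below background at day 7.

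The largest falls by day 21 included genes that had been high in the day 7 cells. Slc13a4 returned from 12.40 ± 0.04 to 7.70 ± 0.15, a log2 change of -4.70 ± 0.13. Trh, the precursor of thyrotropin-releasing hormone, changed by -4.20 ± 0.13, and Dgkk, a diacylglycerol kinase, by -4.17 ± 0.22. Dnmt3b, a de novo DNA methyltransferase, changed by -4.09 ± 0.13, Gldc of the glycine cleavage system by -4.04 ± 0.13 and Prtg, protogenin, by -3.69 ± 0.13. The limma adjusted p of these genes was at most 4.29e-07 (Dgkk). Trh lay below background at day 21, so the size and rank of its fall are set against a floor.

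Of 29 hepatic plasma protein genes, 18 rose, 4 fell and 7 did not pass at day 21 against day 7 (20 and 4 adjusted over the list alone; camera adjusted p = 2.85e-08). After Alb, the largest changes were those of Vtn, vitronectin (4.07 ± 0.10), and Ambp, the precursor of alpha-1-microglobulin (3.35 ± 0.19). Of 21 hepatoblast genes, 14 rose, 3 fell and 4 did not pass (15 and 3 adjusted over the list alone; camera adjusted p = 1.86e-05). The liver transcription factor Onecut1 rose by 3.37 ± 0.19, whereas Tbx3 changed by -2.74 ± 0.13. Of 28 xenobiotic and glutathione genes, 14 rose, 1 fell and 13 did not pass (19 and 2 adjusted over the list alone; camera adjusted p = 2.81e-08). Gsta3, a glutathione transferase, rose by 4.62 ± 0.13 and Ephx1, epoxide hydrolase, by 4.55 ± 0.19. Of 23 acute phase genes, 14 rose, 0 fell and 9 did not pass, the same as adjusted over the list alone, with Lbp, the lipopolysaccharide-binding protein, at 3.54 ± 0.16 (camera adjusted p = 1.41e-08). By contrast, of 36 genes for hepatocyte enzymes 6 rose, 2 fell and 28 did not pass (6 and 2 adjusted over the list alone), and neither camera nor fry called the list (fry adjusted p = 0.0868). Its median was -0.02 and its mean 0.17, and the median changed sign with the scaling. Adh1 (4.14 ± 0.15) and Arg1 (1.24 ± 0.17) were among the enzymes that rose, and 7 of the 36 were above background at day 21.

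Of 33 visceral endoderm genes, 23 fell, 5 rose and 5 did not pass at day 21 against day 7, with the same counts of 23 and 5 adjusted over the list alone (camera adjusted p = 1.12e-09). Besides Slc13a4, large falls were those of Spink1, a protease inhibitor (-3.15 ± 0.12), and Apom (-3.10 ± 0.27). At day 21, 32 of the 33 were still above background. Of 27 lysosome and endocytosis genes, 12 fell, 4 rose and 11 did not pass (14 and 4 adjusted over the list alone), with Ctsh at -2.24 ± 0.13. Compared with other genes, the list had a camera adjusted p of 5.18e-04, with adjusted p = 0.243 with an estimated correlation. Apolipoprotein and lipid transport genes divided into 9 that rose and 12 that fell among 23, the same as adjusted over the list alone. Fabp1, a liver and gut fatty acid carrier, rose by 3.33 ± 0.17 while Apob changed by -2.50 ± 0.16. Camera did not call the list, and fry called it downward (adjusted p = 8.88e-04). Of 19 cholesterol synthesis genes, 13 fell, 0 rose and 6 did not pass (16 and 0 adjusted over the list alone), with Cyp51 at -0.93 ± 0.17 and Srebf2, a regulator of the pathway, at -0.69 ± 0.09. For this list the camera adjusted p was 1.57e-07, with adjusted p = 0.0515 with an estimated correlation.

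Most stromal genes and part of the epithelial genes rose in this interval. Of 26 mesenchyme and fibroblast genes, 20 rose, 1 fell and 5 did not pass, the same as adjusted over the list alone. After Dcn the largest rises were those of Lum, another matrix proteoglycan (4.77 ± 0.29), Col1a1, a fibrillar collagen (3.80 ± 0.25), and Postn (3.71 ± 0.29). This list had a camera adjusted p of 2.12e-14, with adjusted p = 0.104 with an estimated correlation. Of 27 genes of epithelial junctions and keratins, 14 rose, 1 fell and 12 did not pass (17 and 2 adjusted over the list alone), with Cldn4 at 3.14 ± 0.20 and Krt19 at 1.98 ± 0.15. As a list they had a camera adjusted p of 7.30e-07, with adjusted p = 0.237 with an estimated correlation. Of 29 intestine genes, 12 rose, 2 fell and 15 did not pass (13 and 2 adjusted over the list alone; camera adjusted p = 2.84e-04). Krt20 rose by 3.64 ± 0.22 and Cdh17, an intestinal cadherin, by 3.62 ± 0.18. Of 17 genes of epithelial-mesenchymal transition, 10 rose, 2 fell and 5 did not pass (10 and 3 adjusted over the list alone), with Tnc at 2.26 ± 0.24. Camera gave this list an adjusted p of 0.00109, with adjusted p = 0.328 with an estimated correlation.

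Most stress and interferon genes were higher at day 21, and most genes of DNA replication and mitosis were lower. The camera calls of the replication and mitosis lists did not hold with an estimated correlation. Of 24 immediate early and dissociation stress genes, which respond within minutes to handling of cells, 20 rose, 1 fell and 3 did not pass, the same as adjusted over the list alone. Nr4a1, Atf3 and Fosb rose by 2.85 ± 0.10, 2.84 ± 0.15 and 2.08 ± 0.11 (camera adjusted p = 1.16e-15). Of 24 interferon response genes, 18 rose, 0 fell and 6 did not pass, the same as adjusted over the list alone (camera adjusted p = 4.47e-15). Rtp4 rose by 3.23 ± 0.15, Oasl2 by 2.78 ± 0.10 and Ifih1 by 2.31 ± 0.15. Of 17 cell cycle inhibitors and p53 targets, 10 rose, 0 fell and 7 did not pass (11 and 0 adjusted over the list alone; camera adjusted p = 2.97e-06), with the kinase inhibitor Cdkn1a at 1.70 ± 0.09. Of 29 DNA replication genes, 25 fell, 0 rose and 4 did not pass, the same as adjusted over the list alone, with Mcm10 at -1.16 ± 0.11. By camera the adjusted p was 2.19e-13, with adjusted p = 0.0639 with an estimated correlation. Of 31 mitosis genes, 22 fell, 0 rose and 9 did not pass (25 and 0 adjusted over the list alone), with Cdc20 at -1.05 ± 0.14. For these the camera adjusted p was 2.35e-10, with adjusted p = 0.142 with an estimated correlation.

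Part of the pluripotency and epiblast genes and most BMP targets were lower at day 21 than at day 7. Of 29 pluripotency genes, 13 fell, 4 rose and 12 did not pass (14 and 5 adjusted over the list alone), with Lin28a at -3.17 ± 0.10 and Sall4 at -2.50 ± 0.11. Compared with other genes, the list had a camera adjusted p of 0.00385, with adjusted p = 0.166 with an estimated correlation. Of 22 epiblast and primitive streak genes, 12 fell, 0 rose and 10 did not pass, the same as adjusted over the list alone, with Lhx1 at -2.74 ± 0.18 and Otx2 at -2.02 ± 0.15. For this list the camera adjusted p was 1.35e-06, with adjusted p = 0.0549 with an estimated correlation. Of 16 targets of BMP signalling, 11 fell, 0 rose and 5 did not pass, the same as adjusted over the list alone, with Id3 at -1.98 ± 0.16 and Smad6 at -1.28 ± 0.16 (camera adjusted p = 7.15e-06). Among the anchors, Hnf4a changed by -1.03 ± 0.18, Gata4 by -1.13 ± 0.13, Sox17 by -0.63 ± 0.10, Ttr by -0.82 ± 0.14, Apoa1 by -0.54 ± 0.11 and Nanog by -1.45 ± 0.21. Cdh1, E-cadherin, rose by 0.99 ± 0.16. Changes of Foxa2 (-0.24 ± 0.15), Gata6 (0.03 ± 0.11), Pou5f1 (-0.51 ± 0.17) and Mki67 (-0.36 ± 0.13) did not pass.

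Of the remaining markers of other cell types, 8 of 24 endothelial genes fell and 0 rose at day 21 against day 7 (10 down and 1 up adjusted over the list alone), with the receptor Kdr at -1.25 ± 0.21. This list had a camera adjusted p of 2.46e-04, with adjusted p = 0.166 with an estimated correlation. Lists of cardiac and skeletal muscle (2 of 28 up, 6 down), erythroid cells (0 of 14 up, 1 down), pancreas (2 of 24 up, 5 down) and trophoblast (3 of 18 up, 4 down) were not called by camera, and their counts were the same adjusted over the list alone. Neural genes (5 of 23 up, 7 down, or 6 and 8 adjusted over the list alone) were not called by camera either. By fry, muscle (adjusted p = 0.00534), pancreas (0.00921), neural (0.0345) and erythroid genes (0.0496) were called downward, and trophoblast genes were not (0.647). Of 25 leukocyte genes, 5 rose and 1 fell, the same as adjusted over the list alone. They included Cd14, a lipopolysaccharide co-receptor (3.48 ± 0.21), and Csf1r (1.51 ± 0.11), and 9 of the 25 were above background at day 21. Camera did not call that list and fry called it upward (adjusted p = 0.0108), while its median of 0.02 changed sign with the scaling.

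**Figure D2:**
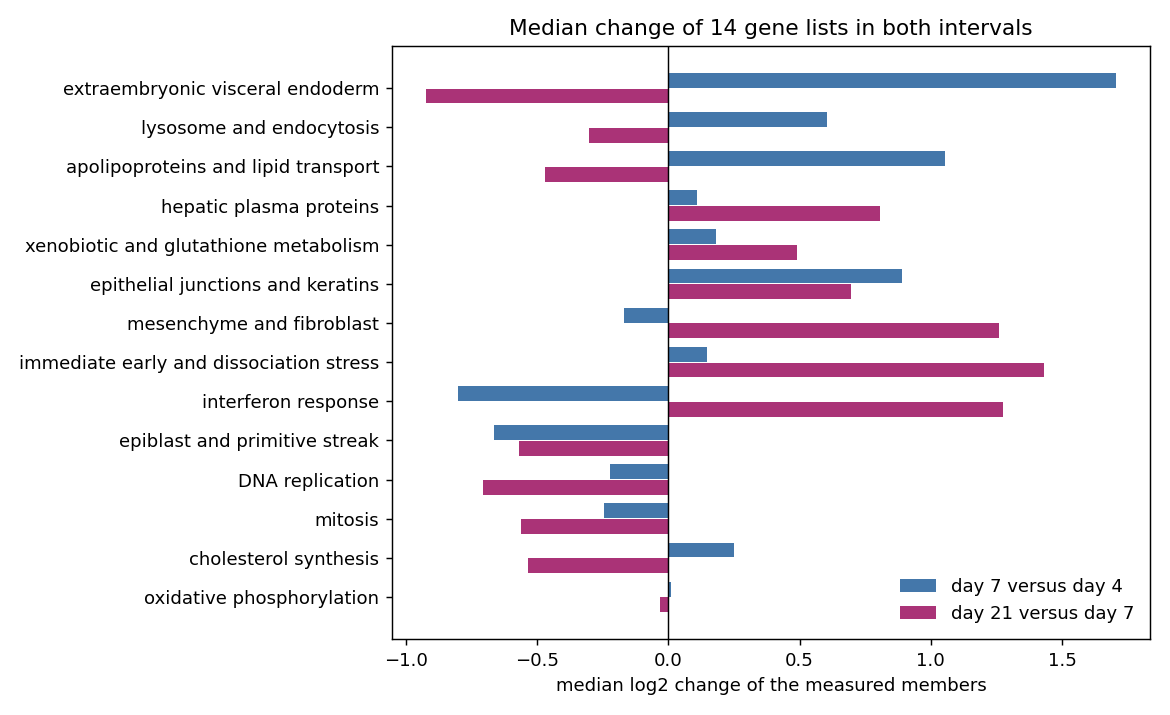
Median log2 change of the measured members of 14 gene lists (horizontal axis) between days 4 and 7 and between days 7 and 21. The visceral endoderm list has a median of 1.70 in the first interval and -0.92 in the second, the interferon list -0.80 and 1.27, and the mesenchyme list -0.17 and 1.26. The small bars of oxidative phosphorylation change sign with the scaling of the arrays in the second interval.

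In all, 5106 genes (23.0%) were called between days 7 and 21, 2740 higher (53.7%) and 2366 lower. With each array centred on its median, only 37.6% of the calls were higher. Centring on the gene medians moved the median change of all genes from -0.03 to -0.13, and from -0.03 to -0.14 between days 4 and 21. Small changes are to be read relative to those shifts. Changes of at least 2-fold numbered 1030 upward and 400 downward, and the groups did not overlap for 7879 genes, against 10% of genes by chance. Camera called 26 of 48 lists, 15 upward and 11 downward. Of these, 10 held with an estimated correlation: visceral endoderm, hepatoblast, hepatic plasma proteins, intestine, cell cycle inhibitors, BMP targets, immediate early, xenobiotic, acute phase and interferon genes.

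Over the whole period from day 4 to day 21, many hepatic plasma protein, epithelial and stromal transcripts rose. Most listed epiblast, primitive streak and cell division transcripts fell. The camera calls of the epithelial, stromal and mitosis lists did not hold with an estimated correlation. Afp rose 163-fold from 5.72 ± 0.18 to 13.07 ± 0.11 (log2 signal, mean ± SD, n = 3 arrays per day), with a limma adjusted p of 2.26e-10. Krt15 rose 93.6-fold, Dcn 89.6-fold, Alb 73.9-fold, Ambp (probe set 17426237) 53.5-fold and Upk1b 46.2-fold. The day 4 means of all of these were below background. Tdgf1 (probe set 17531685) changed by -6.19 ± 0.10 on the log2 scale and Lhx1 (17267039) by -5.46 ± 0.18, to levels below background. Aplnr (-4.88 ± 0.17), Trh (-4.83 ± 0.13), Eomes (-4.42 ± 0.13) and Fndc3c1 (-4.17 ± 0.16) followed. Of these, Trh, Eomes and Fndc3c1 also ended below background, so the sizes and ranks of such falls are set against a floor.

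Of 29 hepatic plasma protein genes, 22 rose, 1 fell and 6 did not pass at day 21 against day 4 (23 and 1 adjusted over the list alone; camera adjusted p = 2.44e-16). The number above background was 3 at day 4 and 21 at day 21. Of 36 genes for hepatocyte enzymes, 7 rose, 3 fell and 26 did not pass, with the same counts of 7 and 3 adjusted over the list alone. Camera did not call that list and fry called it upward (adjusted p = 0.0189), while its median of 0.02 changed sign with the scaling. Of 27 genes of epithelial junctions and keratins, 26 rose, 0 fell and 1 did not pass, the same as adjusted over the list alone, with Esrp2, an epithelial splicing regulator, at 2.87 ± 0.11. As a list they had a camera adjusted p of 3.41e-18, with adjusted p = 0.0508 with an estimated correlation. Of 26 parietal endoderm and basement membrane genes, 18 rose, 4 fell and 4 did not pass, the same as adjusted over the list alone, with the laminin chain Lamc1 at 1.96 ± 0.11. These had a camera adjusted p of 2.84e-07, with adjusted p = 0.104 with an estimated correlation. All 29 DNA replication genes fell, also adjusted over the list alone, with Mcm10 at -1.59 ± 0.11 and Gins1 at -1.50 ± 0.10 (camera adjusted p = 2.16e-17). Of 31 mitosis genes, 30 fell, 0 rose and 1 did not pass, the same as adjusted over the list alone, with Bub1 at -1.66 ± 0.14. Camera gave this list an adjusted p of 1.31e-14, with adjusted p = 0.0648 with an estimated correlation. All 29 replication and all 31 mitosis genes were still above background at day 21. Of 22 epiblast and primitive streak genes, 19 fell, 0 rose and 3 did not pass, the same as adjusted over the list alone (camera adjusted p = 7.59e-13). Of 13 Nodal and Activin genes, 9 fell, 1 rose and 3 did not pass (9 and 2 adjusted over the list alone; camera adjusted p = 1.03e-04), with Foxh1 at -2.76 ± 0.16. Visceral endoderm genes stayed above day 4 at day 21, with 23 of 33 higher, 5 lower and 5 not passing, the same as adjusted over the list alone (camera adjusted p = 5.72e-10).

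Interferon, mesenchymal and other marker lists were also compared over the whole period, some of them mixed and others moving mostly in 1 direction. Of 24 interferon response genes, 9 were higher, 4 lower and 11 did not pass (10 and 6 adjusted over the list alone), with Psmb8 of the immunoproteasome at -1.88 ± 0.12 and Irf9 at 1.20 ± 0.11. Camera did not call the list, and fry called it upward (adjusted p = 0.0397). Of 17 genes of epithelial-mesenchymal transition, 5 rose, 6 fell and 6 did not pass (6 and 6 adjusted over the list alone), with Cdh2 at -3.54 ± 0.19 and Mmp14 at 1.11 ± 0.15. That list was called by neither camera nor fry (fry adjusted p = 0.0790), its median was 0.01 and its mean -0.14, and the median changed sign with the scaling. Of 26 mesenchyme and fibroblast genes, 16 rose, 4 fell and 6 did not pass (19 and 4 adjusted over the list alone), with Igfbp5 at 5.35 ± 0.11. By camera the adjusted p was 2.10e-07, with adjusted p = 0.201 with an estimated correlation. Of 25 leukocyte genes, 7 rose, 0 fell and 18 did not pass, the same as adjusted over the list alone, with a camera adjusted p of 0.00969 and adjusted p = 0.190 with an estimated correlation. Trophoblast genes (3 of 18 up, 4 down, the same as adjusted over the list alone) had a median of -0.07 and a mean of 0.05, and were called by neither camera nor fry (fry adjusted p = 0.751). Lists of cardiac and skeletal muscle (8 of 28 up, 2 down), endothelium (1 of 24 up, 5 down), erythroid cells (0 of 14 up, 3 down) and neural genes (2 of 23 up, 8 down) were not called by camera, with the same counts adjusted over the list alone. Fry called muscle genes upward (adjusted p = 0.00472) and endothelial (0.0207), erythroid (0.0127) and neural genes (0.00117) downward. Pancreas genes (2 of 24 up, 3 down, or 1 and 3 adjusted over the list alone) were called by neither camera nor fry (fry adjusted p = 0.0755). Of 29 pluripotency genes, 5 rose and 14 fell (5 and 15 adjusted over the list alone), with a camera adjusted p of 0.00588 and adjusted p = 0.154 with an estimated correlation. Of 29 intestine genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 5.84e-07).

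Among the anchors not given above, Cdh1 rose by 1.37 ± 0.16 between days 4 and 21, Hnf4a by 1.63 ± 0.18, Ttr by 3.48 ± 0.14, Apob by 3.33 ± 0.16, Apoa1 by 1.67 ± 0.11, Sox17 by 0.84 ± 0.10 and Gata4 by 0.51 ± 0.13. Foxa2 (0.12 ± 0.15) and Gata6 (0.07 ± 0.11) did not pass in this or either other comparison. Nanog changed by -2.48 ± 0.21. Pou5f1 changed by -0.61 ± 0.17 with a limma adjusted p of 0.0230, which became 0.0869 without day 4 replicate 1, 0.0638 without day 21 replicate 2 and 0.0799 without day 21 replicate 3. Mki67 changed by -0.45 ± 0.13 with a limma adjusted p of 0.0219. That became 0.0662 and 0.0809 without day 4 replicates 1 and 2, and 0.0566 and 0.0663 without day 21 replicates 1 and 3.

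In all, 6448 genes (29.1%) were called between days 4 and 21, 3328 higher (51.6%) and 3120 lower, and 36.8% of calls were higher after median centring. Changes of at least 2-fold numbered 1207 upward and 569 downward, and the groups did not overlap for 8966 genes, against 10% of genes by chance. Camera called 34 of 48 lists, 23 upward and 11 downward, and 17 calls held with an estimated correlation.

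Both intervals together called 1647 genes, and more of them turned than continued. There were 591 genes that rose and then fell, 526 that fell and then rose, 277 that rose in both intervals and 253 that fell in both. Independent lists of these sizes would share 165, 177, 191 and 153 genes. Of the 33 visceral endoderm genes, 22 rose and then fell, and of the 24 interferon response genes, 15 fell and then rose. The genes with the strongest movement in each class, chosen after their values were seen, were Slc13a4 and Gramd1b (up, then down), Ifi27 and Oasl2 (down, then up), Igfbp5 and Afp (up in both), and Lhx1 and Tdgf1 (down in both). Ifi27 changed by -3.40 and then by 5.04, and Gramd1b by 3.55 and then by -3.19.

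Across genes, which are not independent replicates, the log2 changes of the intervals had a correlation of -0.25 and a covariance of -0.0616. With no effect, the shared day 7 arrays alone gave -0.50 and -0.0117 in simulation. The correlations are not comparable in size, because changes between the days widen the observed spread. The observed covariance was further from 0 than the simulated one, so in this simulation the shared arrays alone did not give it. The 3 day 7 arrays were not divided between the intervals, so part of the excess of genes that turned may come from the shared arrays.

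**Figure D3:**
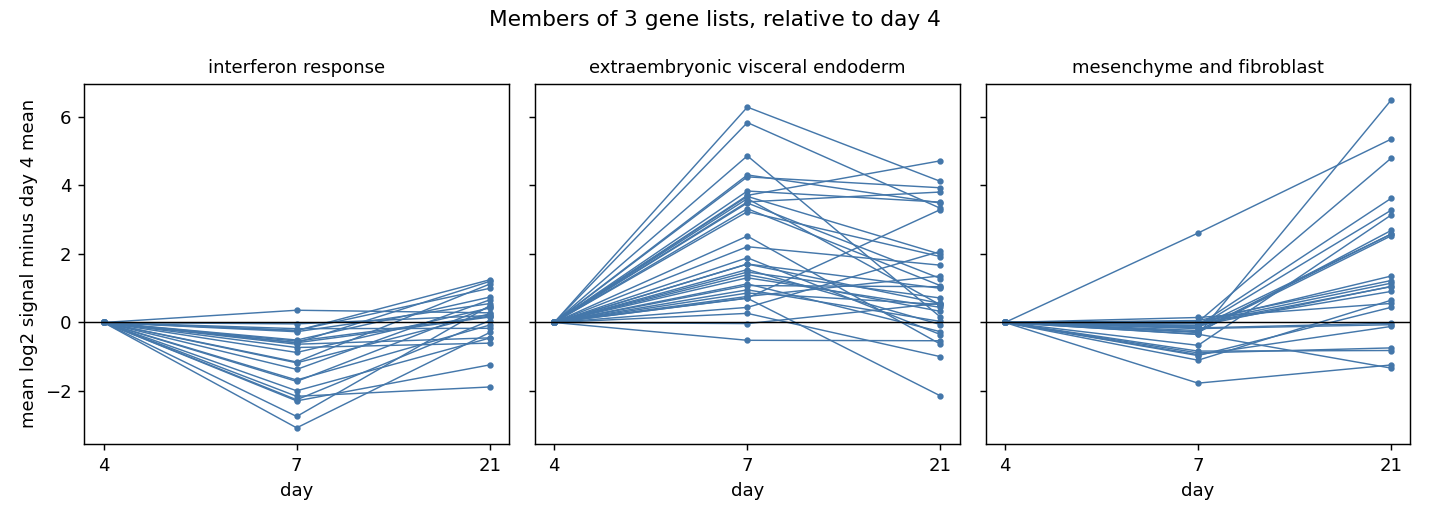
Mean log2 signal minus the day 4 mean (vertical axis) at days 4, 7 and 21 (horizontal axis, not to scale in time) for each measured member of 3 gene lists. Each line is 1 gene, with means over 3 arrays. Of 24 interferon genes 18 fell by day 7 and 18 rose by day 21, of 33 visceral endoderm genes 29 rose and 23 fell, and of 26 mesenchyme genes 20 rose by day 21.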

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

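The regroupings of arrays were planned before the data were examined, whereas the tests of explanations for the 3 patterns were chosen only after the result was seen. Between days 4 and 7, 1 of the 10 splits of the 6 arrays, the real one, gave as many as 2983 genes, and the highest other split gave 0. Between days 7 and 21 it was again 1 of 10, with 5106 genes against 0, and between days 4 and 21 also 1 of 10, with 6448 against 0. For the gene lists the real splits gave 29, 26 and 34 calls, each the highest of 10, and the highest other splits gave 16, 18 and 24. Camera with its preset correlation thus called many lists in groupings that mix the days. Each such grouping set 2 arrays of 1 day and 1 of the other against the rest, so part of the day difference remained. These list calls therefore do not measure how often camera calls unchanged lists. With 10 splits the share cannot fall under 0.05. For genes called in both intervals, 3 of 100 splits of the 9 arrays, the real one included, gave at least 1647 genes. That share is under 0.05, but only 5 of the 100 splits, the real one included, gave any gene. It therefore shows that the days separate, and it does not test chance overlap between the intervals. The highest other split gave 2675. The 2 other splits that reached the real count both put the 3 day 21 arrays together as the middle group, with days 4 and 7 mixed on either side, so these larger counts follow the structure of the samples, in which day 21 stands apart.

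Afp lay at background in cells sorted for the Afp reporter at day 4, at 5.72 ± 0.18 (n = 3 arrays), with the 3 values between 5.62 and 5.93. A probe set that does not respond to Afp is argued against by its day 21 mean, which was 7.04 log2 units above the olfactory receptor level. Exchange of single arrays between days is argued against by correlations, whose lowest within a day was 0.984 and whose highest between days was 0.971. Other cells in the day 4 sort that carry no Afp transcript may account for the level and cannot be told apart from reporter activity ahead of the endogenous gene, because 15 of 19 endoderm transcription factors were above background at day 4 against 17 at day 7, and cells that never make Afp also express such factors. A biological difference between the days stays open and was not tested.

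Most mesenchyme and fibroblast genes rose between days 7 and 21 in cells sorted for a reporter of endoderm. The camera call of this list did not hold with an estimated correlation. The rise did not depend on the choice of scaling, and the median change of the 26 genes was at least 1.16 after quantile normalization and after median centring. RMA had already brought the arrays to a common distribution, and centring shifts all genes of an array alike. These scalings could therefore change the rise little and do not decide on scaling as a cause. Mesenchymal cells in the day 21 sort remain a candidate source: members that are not secreted matrix had a median change of 0.47 with 5 of 10 risen, against 2.77 with 15 of 16 for secreted matrix, and 19 of the 26 genes were above background already at day 7. At day 21 the members with the highest signals, which do not rank transcripts of different probe sets, were Igfbp5 (11.59 ± 0.13), Dcn (11.56 ± 0.62) and Col1a1 (11.39 ± 0.42), and the SD of Lum (0.68) and Postn (0.71) exceeded that of Afp (0.11). A gate on the reporter is meant to remove such cells, but their share and the purity of the sort are not known. They therefore cannot be told apart from matrix gene expression by reporter-positive cells.

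Most interferon response genes fell by day 7, and most rose by day 21. The fall did not depend on the choice of scaling, and the median change at day 7 was -0.80 or further from 0 under both other scalings. As for the mesenchyme genes, these scalings could change it little and do not decide on scaling as a cause. Leukocytes in the day 4 sort cannot be told apart from a response of the sorted cells. Only 4 of 25 leukocyte markers were above background at day 4, too few for the test, and 0 fell by limma's test. A gate on the reporter is meant to remove leukocytes, but the purity of the sort is not known. Ptprc, the pan-leukocyte antigen, was at 4.40 ± 0.01 at day 4, and the markers with the highest signals, Cd68 and Lcp1, were at 8.36 ± 0.19 and 7.25 ± 0.25 and rose by day 7. Handling or labelling that differed between days cannot be told apart from the days themselves.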

How the results depend on the processing

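The tests with a filter at the olfactory receptor level, and with quantile normalization for the gene lists, were chosen after seeing the data. No called result reversed: of 9920 alternatives for 553 named gene results, 9733 left the call as it was, 163 ended one (36 results), 24 made one and 0 reversed. Of 2160 alternatives for 144 list results, 2035 left the call, 81 ended one, 44 made one and 0 reversed. Total counts moved by more than 1.5 times only under stricter thresholds and with an estimated correlation. By direction, between days 7 and 21, so did the lower genes after median centring (3760 in place of 2366). That centring moved the median change of all genes from -0.03 to -0.13. The lists called downward by fry also moved so far (18 in place of 11), and the cause of that was not tested. A change of at least 2-fold left 756 genes between days 4 and 7, 1430 between days 7 and 21, 1776 between days 4 and 21 and 316 in both intervals. An adjusted p under 0.01 left 1762 and 3297 genes in the first and second interval and 885 in both. With an estimated correlation, 6, 10 and 17 lists were called in place of 29, 26 and 34, and fry called 36, 39 and 43. Median centring gave 2905, 6026 and 7305 genes. The stricter thresholds by construction call fewer genes. For the lists, fewer calls with an estimated correlation may come from members that vary together between arrays of a day. They may also come from other parts of that test, and these were not separated.

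Leaving out 1 array at a time gave 2176 to 3285 genes between days 4 and 7, 4108 to 5048 between days 7 and 21, 5423 to 6255 between days 4 and 21, and 1183 to 1718 in both intervals. Restricting the test to 13188 genes above the olfactory receptor level on at least 1 day gave 3592, 5450 and 6667 genes and 2090 in both. Signal over background limits what can be called near that level, to an extent that was not tested. The labels do not say that the replicate numbers pair the samples, and not every same-numbered pair correlated above 0.1. Correlations of same-numbered arrays' deviations ran from -0.054 to 0.263, with 2 of 9 pairs above 0.1, and 0 arrays correlated best with their own number on both other days. Between days 7 and 21, however, the same-numbered pairs (0.078, 0.139 and 0.263) all lay above the highest other pair (0.074), a hint from the data of shared numbers there. With the replicate number as a block, 2895, 5041 and 6413 genes and 1604 in both intervals were called, and 29, 26 and 34 lists.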

Other observations

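The tests of 3 further gene lists in the last paragraph were specified before the values of their members were seen, but those lists were chosen only after the result that led to them was seen. Most changes among fatty acid oxidation and iron handling genes between days 4 and 21 were rises. So were most changes in the insulin-like growth factor axis between days 7 and 21, though its camera call did not hold with an estimated correlation. Oxidative phosphorylation genes were not called as a list by camera or fry. Of 24 mitochondrial fatty acid oxidation and peroxisome genes, 13 rose, 0 fell and 11 did not pass between days 4 and 21 (15 and 0 adjusted over the list alone; camera adjusted p = 1.60e-06, a call that held with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose by 4.20 ± 0.18 and Ppargc1a, a coactivator of mitochondrial genes, by 3.69 ± 0.21 (log2 change ± SE, n = 3 arrays per day). Of 19 iron and metal handling genes, 11 rose, 1 fell and 7 did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 4.81e-06, which held). Cp, ceruloplasmin, rose by 3.17 ± 0.18 and Slc40a1, the iron exporter ferroportin, by 2.85 ± 0.21. Of 18 insulin-like growth factor axis genes, 10 rose, 3 fell and 5 did not pass between days 7 and 21, the same as adjusted over the list alone, with Igfbp7 at 4.39 ± 0.15 and Igfbp1 at 3.83 ± 0.20. Compared with other genes, the list had a camera adjusted p of 1.01e-04, with adjusted p = 0.166 with an estimated correlation. Of 30 oxidative phosphorylation genes, all above background, limma called 1 between days 4 and 7, 0 between days 7 and 21 and 3 between days 4 and 21, against 0, 0 and 1 adjusted over the list alone. Between days 7 and 21, 2 had an unadjusted p under 0.05 and the fry adjusted p was 0.769, and the sign of the list's median changed with the scaling in that interval and over the whole period.

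Patterning and chromatin genes moved in both directions between days 4 and 21. Of 14 anterior visceral endoderm genes, 9 fell, 1 rose and 4 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 4.42e-05, which held with an estimated correlation). Dkk1, a Wnt antagonist, changed by -2.42 ± 0.15 and Cer1, an antagonist of Nodal and BMP, by -2.05 ± 0.18. Of 17 FGF-ERK genes, all passed, 6 up and 11 down, the same as adjusted over the list alone. The receptors Fgfr3 and Fgfr2 rose by 3.35 ± 0.19 and 3.31 ± 0.14, while the feedback inhibitors Il17rd and Dusp4 changed by -2.59 ± 0.12 and -2.28 ± 0.11. The camera adjusted p of that list was 0.0252, with adjusted p = 0.203 with an estimated correlation and 0.115 after median centring. Of 15 Wnt targets, 5 rose and 7 fell, the same as adjusted over the list alone, with Lef1 at -3.37 ± 0.13 and Rnf43 at 2.78 ± 0.12. Camera did not call that list, and fry called it downward (adjusted p = 6.80e-04). Of 24 chromatin regulators, 13 fell, 2 rose and 9 did not pass (14 and 2 adjusted over the list alone). Smarca2, an ATPase of SWI/SNF complexes, rose by 2.10 ± 0.13, and Chd1 changed by -0.96 ± 0.11. For this list the camera adjusted p was 0.00629, with adjusted p = 0.2999 with an estimated correlation. Of 23 DNA methylation and germline genes, 6 rose and 4 fell, the same as adjusted over the list alone, with Dnmt3b at -3.39 ± 0.13 and Tet2, a methylcytosine dioxygenase, at 1.82 ± 0.14. Again camera did not call the list and fry called it downward (adjusted p = 0.00486). Of 31 Hox genes, 1 rose and 2 fell, the same as adjusted over the list alone, with Hoxb1 at -1.58 ± 0.15, and 2 of the 31 were above background at day 21. Neither camera nor fry called that list (fry adjusted p = 0.400), its median of 0.02 and mean of -0.04 differed in sign, and the median changed sign with the scaling.

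Because Krt15, Krt17, Upk1b, Dcn and Cym were among the largest rises between days 7 and 21, 3 lists that hold none of them were tested for wider programs. Of 22 other stratified and urothelial epithelium genes, 17 rose and 0 fell (77.3% risen, against 12.4% of all genes), with a camera adjusted p of 2.13e-15 over the 3 lists and adjusted p = 0.00187 with an estimated correlation. Among the risen genes, Krt16 and Dsg3 were still below background at day 21, at 5.82 and 5.94. Upk3b also stands in the mesothelium list and Psca in the stomach list, so the lists are not independent. Krt14, Sprr1a and Upk1a rose by 3.52 ± 0.16, 3.66 ± 0.25 and 2.18 ± 0.12 between days 7 and 21. A hypothesis from this is that the cells sorted at day 21 may include a stratified or urothelial epithelial program, within the same cells or in others of the sort. Arrays of pooled cells cannot decide between these, which profiles of single cells or staining of the reporter with a keratin would. Of 17 other mesothelium genes, 7 rose and 1 fell (41.2% risen), with Msln at 3.22 ± 0.20. Of 27 other stomach genes, 8 rose and 1 fell (29.6% risen), with Muc1 at 3.34 ± 0.13. Both had a camera adjusted p of 0.00739, with adjusted p = 0.0752 and 0.0982 with an estimated correlation, and these shares lie between the bounds set for and against a program, so neither was decided.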
